A study of Mus musculus with 12 samples.

How the data were processed

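Messenger RNA was measured by sequencing in 12 libraries of mouse embryonic stem cells of the E14Tg2a line (strain 129/Ola). The cells were wild type (WT) or carried, on both alleles, a deletion of a regulatory region of Tcf15, a gene for a basic helix-loop-helix transcription factor; the deleted line, delta 0.7 in the labels, is called delta here. Each genotype was sampled in 2i medium with LIF (0 h) and after 12 and 24 h on fibronectin in N2B27 with Activin, bFGF and KOSR, the conditions that turn naive stem cells into epiblast-like cells. Each of the 6 groups held 2 libraries. The labels do not say that the replicates were separate cultures. P-values of the model fit thus measure only the spread between these samples, which may be technical. The delta columns carry the name of a single clone, so genotype and clone cannot be separated. Per the labels' protocols, RNA was purified with RNeasy Plus columns, mRNA was taken from 1 µg of total RNA with oligo-dT beads, and libraries were made with the NEBNext Ultra II kit.

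Values were taken as FPKM (fragments per kilobase of exon, scaled to the depth of the library) as the authors deposited them, in a table of 47729 genes with Ensembl identifiers. The submitters' processing notes list cutadapt (version not given), STAR 2.5.2b, featureCounts 1.5.1, edgeR 3.16.5 and genome build mm10, without the role or order of each. Whether reads were counted by strand is not given in the sources used here, so overlapping genes on opposite strands may share reads. The low FPKM values were whole multiples of the worth of 1 read. Gene lengths from GENCODE M21, or found from the steps for 5708 genes, gave whole reads within a tolerance of 0.01 for 100% of the 28657 genes above 0 in at least 1 library; 80.1% of these used the annotated length. The FPKM scale had been set by an effective library size of 75.5% to 107% of the recovered reads. The recovered depth was 9740851 to 17571255 reads per library (median 12189883), and 1 read per kilobase was worth 0.0569 to 0.111 FPKM. FPKM is not a count, so recovered reads served only for depth, for shares of reads and for an alternative test with voom weights.

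The analysis ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with an FPKM of at least 1 in at least 2 libraries were kept (13981). Their log2(FPKM + 1) values entered a single limma model with a mean for each of the 6 groups, without further scaling and without a replicate block, and with moderated variances that follow a mean-variance trend (6 residual and 3.11 prior degrees of freedom). The pseudocount of 1 understates the changes of low genes. All 2-sided p-values of a contrast were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The 10 contrasts were delta against WT at each time and averaged over times, the change from 0 h to 12 and 24 h in each genotype, and the difference between genotypes in each change. Standard errors (SE) are those of the model, and standard deviations (SD) are over the 2 libraries of a group.

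The following choices were fixed before the data were examined: the contrasts, the filter, the gene lists, the alternatives and the rule for named genes. That rule took up to 10 rises and 10 falls per contrast (5 each way for the delta changes) among called genes whose libraries did not overlap between groups, with a mean FPKM of at least 5 in the higher group and a symbol that is not a predicted one. It added Tcf15, the neighbours of the deleted region, and up to 4 members with the smallest adjusted p from each list named. Of 29 lists, 27 had the minimum of 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. They covered naive, general and formative pluripotency, primitive streak, primitive endoderm, trophoblast, neural, germline and fibroblast markers, DNA methylation enzymes, FGF/ERK, Activin/Nodal, WNT and BMP targets, adhesion, extracellular matrix, glycolysis, cholesterol synthesis, the amino acid and integrated stress response, p53 targets, cell cycle, heat shock, interferon response, mitochondrially encoded genes, Y-linked genes, imprinted genes and the neighbours of the deleted region. The paraxial mesoderm list had 1 measured member and the 2-cell-like list had 0, so neither was tested. The primitive endoderm list had 7 of 14 members measured. It shares Col4a1, Col4a2, Lama1, Lamb1, Lamc1 and Sparc with the extracellular matrix list. Camera was run again with a correlation estimated from the data, and under that setting no list passed in any contrast; the smallest adjusted p was 0.0889.

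Replicate numbers come from the sample titles. Deviations of WT and delta libraries of the same number and time correlated at 0.70, 0.28 and 0.37 at 0, 12 and 24 h. The p-values of the main fit do not use this pairing. Differences within same-numbered pairs are given beside some of them. A value with the replicate number as a block is given where it changed a call. Chromosome medians were tested by 100000 permutations of genes over 21 chromosomes, with a smallest possible p of 1e-05. A scan for chromosome segments with shifted levels used 7903 genes with a mean FPKM of at least 5 and 1000 permutations, with a smallest possible p of 0.001. Both permutation tests take genes as the units and hold no spread between libraries. Positions come from GENCODE M21 (mm10), where 47224 identifiers were found; 136 symbols in the table were shared by more than 1 identifier.

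The fit was tested on simulated values of the 13981 genes with 200 changed genes. At a single time, 21% to 24% of genes changed by 1 log2 unit between genotypes and 90% to 93% of those changed by 3 were called. For the contrast averaged over times, 69% and 99% were called. With the same changes in delta at 24 h alone, the difference in change from 0 to 24 h called 9% and 72%. False calls among unchanged genes numbered 2, 4 and 13 at 0, 12 and 24 h, 8 averaged over times and 5 for the difference. The simulated noise was independent between libraries, with the same spread at each time for a gene. The real libraries had a larger spread at 0 h and shared deviations, so these shares may not hold for them. No pair of replicate libraries held identical values. Alternatives were another pseudocount, 2 other filters, 2 scalings, the replicate block, no variance trend, fits with only the groups compared, recovered reads with voom weights, and leaving out each library. Leaving out a library outside the groups of a contrast does not change its differences and alters only the estimated spread. Lists and sets of changing genes were also tested with fry, another set test of limma, and its values are given for the sets. Those added after the data were seen were a block within each time, fits without doubtful libraries or times, protein-coding genes only, and fits without a chromosome 14 segment.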

Results

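The data were FPKM values of 12 RNA sequencing libraries from WT and delta mouse embryonic stem cells at 0 h (naive cells in 2i with LIF) and after 12 and 24 h of induction towards epiblast-like cells, with n = 2 libraries in each of the 6 groups. Between 19235 and 22031 genes were above 0 in a library. The libraries differed in ways the groups did not explain. In the replicate 1 libraries at 0 h, ribosomal protein genes took 11.5% (WT) and 13.5% (delta) of reads, against 5.81% to 7.57% in the other 10 libraries. These libraries also stood apart from their partners: the SD of the log2 difference between replicates was 0.66 in WT and 0.83 in delta at 0 h and 0.31 to 0.42 in the later groups. Mitochondrially encoded genes took 0.447% to 0.647% of reads in the replicate 1 libraries and 1.80% to 2.87% in the replicate 2 libraries. Reads of rRNA-like genes made up 8.01% of the delta 0 h replicate 1 library and 3.42% of the WT 12 h replicate 2 library, against 0.217% to 1.13% elsewhere. Principal component 1 held 48.3% of the variance and component 2 held 22.8%.

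The first question was whether the deletion removed Tcf15 expression. In WT cells Tcf15 (ENSMUSG00000068079), whose product is a basic helix-loop-helix transcription factor, stood at 6.31 ± 4.04 FPKM (SD, n = 2) at 0 h, 43.0 ± 20 at 12 h and 77.4 ± 31.1 at 24 h. In delta cells it stood at 1.6 ± 0.789, 1.05 ± 0.0197 and 3.60 ± 1.19 FPKM. The genotype difference was −1.40 log2 units at 0 h, −4.34 at 12 h, −4.06 at 24 h and −3.27 ± 0.27 (SE) averaged over times, and delta was lower in all 6 replicate pairs. With limma the averaged difference passed the threshold (adjusted p = 0.0050), as did that at 12 h (adjusted p = 0.047). The difference at 0 h did not pass (adjusted p = 1) and was −0.81 without WT 0 h replicate 1. That at 24 h did not pass without the block (adjusted p = 0.083) and passed with the replicate block (adjusted p = 0.0012, range over all alternatives 0.0012 to 1). The 12 h call held without either WT 0 h library and was lost without each of the other 10 libraries (adjusted p = 0.084 to 0.72). In WT cells Tcf15 rose by 3.49 log2 units by 24 h (adjusted p = 0.0020), and in delta cells the change was 0.83 (adjusted p = 0.27).

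**Figure D1:**
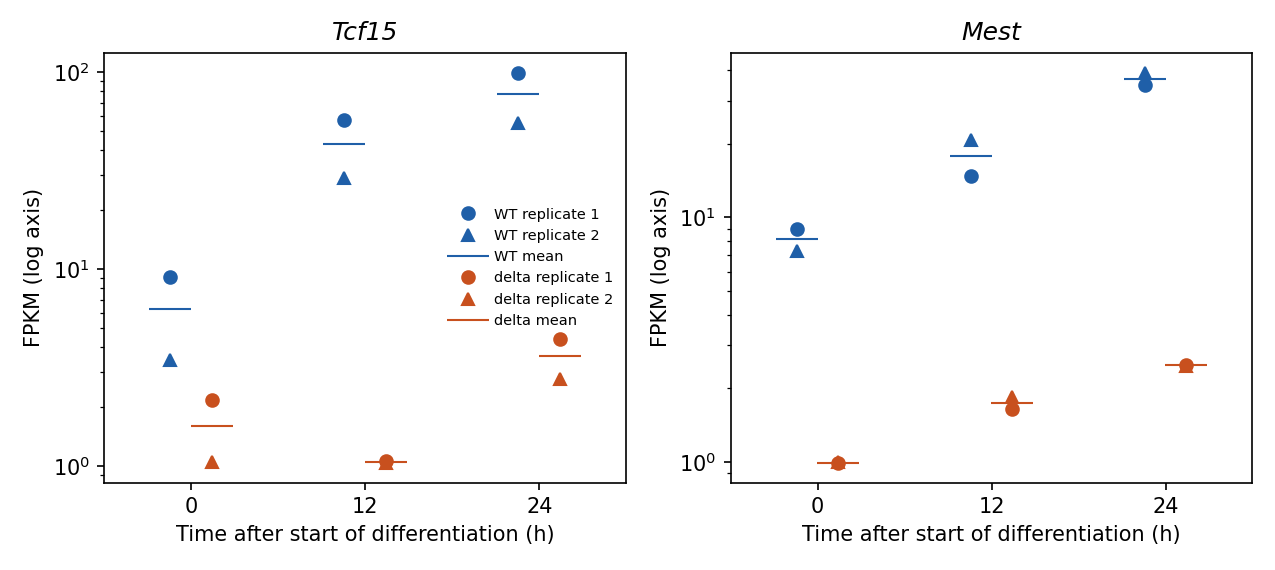
FPKM of Tcf15 and of Mest in each library (log axis) by hours of induction; circles are replicate 1, triangles replicate 2, bars group means, WT blue and delta orange. Tcf15 reached 99.4 and 55.4 FPKM in the WT libraries at 24 h and 4.44 and 2.76 in the delta libraries, and Mest was lower in delta at each time.

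The deleted region is on chromosome 2, from 152177049 to 152177722 (mm10, 674 bp). It overlapped 0 annotated genes and 0 exons in GENCODE M21. Tcf15 lies from 152143561 to 152149097 on the plus strand, and the region begins 33.5 kb from its start and 28.0 kb beyond its end. On the other side the nearest gene was the pseudogene Rps15a-ps7 at 7.6 kb (averaged difference −0.21 log2 units), and the nearest protein-coding gene was Csnk2a1, a catalytic subunit of casein kinase 2, at 49.1 kb (−0.12). Without Tcf15, the 14 measured genes within 500 kb had a median averaged difference of −0.08, from −0.44 (Slc52a3) to 0.88 (Gm27343), and none was called by limma. Srxn1, a sulfiredoxin gene beside Tcf15, differed by −0.25, Trib3 by −0.31 and Sox12 by 0.33. The list of neighbours, which holds Tcf15, was lower in delta at 12 h (camera adjusted p = 0.0063), 24 h (0.0098) and averaged over times (0.024). The list medians were only −0.06, −0.09 and −0.07. Since the target of the deletion lies inside the list, these calls do not show an effect on the other members. These calls were lost with an estimated correlation (adjusted p = 0.22, 0.15 and 0.22 with an estimated correlation), and without single libraries (adjusted p up to 0.20). These were the replicate 1 libraries of the time for 12 h and 24 h, and for the average delta 0 h replicate 2 and each replicate 1 library but that of delta at 12 h.

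**Figure D2:**
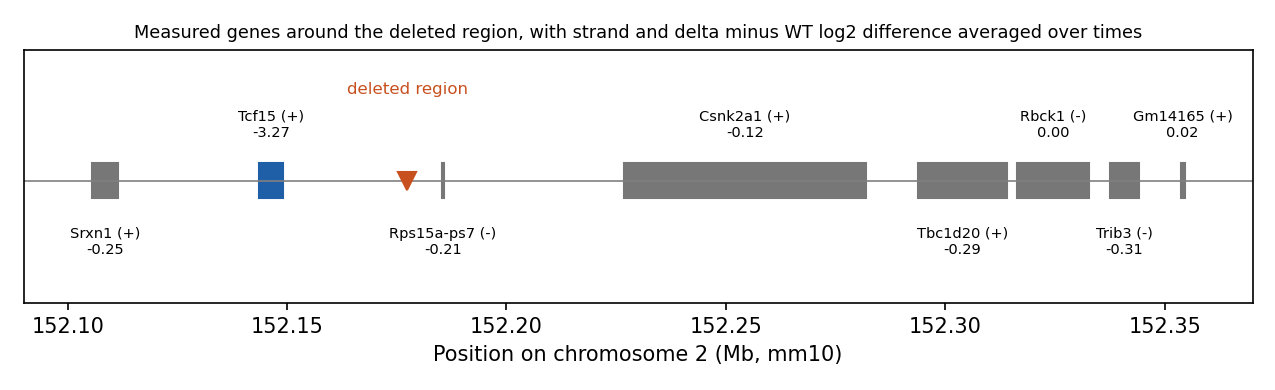
Measured genes of chromosome 2 around the deleted region (x axis, position in Mb, mm10), drawn to scale with their strand and their delta minus WT log2 difference averaged over times. Tcf15 stands at −3.27, and Csnk2a1 on the other side of the deletion at −0.12.

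The change of WT cells during induction served as the reference for the deletion. By 24 h the largest rise was that of Pou3f1, which encodes the POU factor Oct6 of the postimplantation epiblast, from 0.191 ± 0.129 to 55 ± 9.61 FPKM (SD, n = 2; 5.55 ± 0.38 log2 units, SE). Gadd45g, a stress and differentiation gene, rose by 4.73, Myrf by 4.46, the ERK phosphatase gene Dusp4 by 4.11 and the DNA methyltransferase gene Dnmt3a by 3.76. Prss50, Emb, Enpp2, Enpp3 and Cgnl1 completed the 10 largest rises (3.55 to 4.36). The largest fall was that of the WNT target Sp5, from 70.1 ± 24.6 to 0.137 ± 0.0160 FPKM (−5.92 ± 0.50 log2 units). Brachyury (T) changed by −4.00, Cdx1 by −4.59, the STAT3 feedback gene Socs3 by −4.19 and the receptor gene Kit by −3.87; Ly6g6e, Aqp3, Nkx1-2, Nkx6-2 and Trpm1 fell by −3.89 to −4.62. With limma 737 genes rose and 690 fell by 24 h, and 298 rose and 265 fell by 12 h, where Sp5 (−5.52), Nkx1-2 (−4.05) and Ly6g6e (−3.73) already led the falls and Prss50 (3.92), S100a6 (3.72) and Dnmt3l (3.15) were among the rises. Leaving out single libraries moved the total at 24 h between 596 (without WT 24 h replicate 1) and 2458 (without delta 0 h replicate 2), and that at 12 h between 130 (without WT 12 h replicate 1) and 1084 (without delta 0 h replicate 1).

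Formative and early primed epiblast genes rose in WT cells. Their median change was 2.83 log2 units at 24 h, and 12 of 15 were called (13 adjusted over the list alone), with Pou3f1 (5.55), Fgf5 (3.31), Grhl2 (3.22) and Dnmt3b (2.76) as examples (camera adjusted p = 3.7e-15; adjusted p = 0.13 with an estimated correlation). Naive pluripotency genes fell by a median of −2.0. Of these 20 genes 13 fell and 1 rose (14 and 2 adjusted over the list alone), with Socs3 at −4.19, Klf2 at −2.33, Jam2 at −2.24 and Tcl1 at −1.77 (adjusted p = 5.1e-08; adjusted p = 0.13 with an estimated correlation). At 12 h the formative median was already 1.32 (7 called; adjusted p = 2.9e-08; adjusted p = 0.24 with an estimated correlation) and the naive median −0.45 (5 fell, 1 rose; adjusted p = 0.013; adjusted p = 0.38 with an estimated correlation). Among general pluripotency genes 7 of 12 rose by 24 h, with Utf1 at 2.69 (list median 1.18, adjusted p = 3.3e-05; adjusted p = 0.13 with an estimated correlation). Of 3 core pluripotency factors chosen after their values were seen, Nanog fell from 309 ± 37.7 to 65.9 ± 3.64 FPKM, while Pou5f1 (733 and 632 FPKM) and Sox2 (241 and 231 FPKM) were not called.

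Other groups changed in WT cells too. Of 5 measured primitive streak genes 4 fell, T, Sp5, Cdx1 and Gsc (−2.49), with a list median of −4.00 (adjusted p = 3.2e-04; adjusted p = 0.16 with an estimated correlation). FGF/ERK targets had a median of 0.85, and 7 of 15 rose, among them Dusp4, Myc (2.48), Dusp6 (2.43) and Spry4 (1.94) (adjusted p = 5.1e-06; adjusted p = 0.13 with an estimated correlation). DNA methylation enzymes rose (median 0.68), with Dnmt3a (3.76), Dnmt3l (3.50) and Dnmt3b (2.76) as the 3 called members (adjusted p = 7.5e-04; adjusted p = 0.13 with an estimated correlation). Germline genes had a median of 0.94, with Mael (1.31) and Ddx4 (0.89) called (adjusted p = 7.5e-04; adjusted p = 0.39 with an estimated correlation). Genes of the amino acid and integrated stress response fell by a median of −0.88, with 4 of 15 called, among them Nupr1 (−2.31), Asns (−1.88), which makes asparagine, and Trib3 (−1.30) (adjusted p = 0.0032; adjusted p = 0.23 with an estimated correlation). WNT targets (median −0.70, adjusted p = 0.0014) and glycolysis genes (−0.54, adjusted p = 0.0089) fell at 12 h; both calls were lost (adjusted p = 0.38 and 0.46 with an estimated correlation).

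Delta cells changed in many of the same genes. Pou3f1 reached 87.1 ± 2.86 FPKM at 24 h (SD, n = 2; 6.13 log2 units), and Gadd45g (5.73), Myrf (4.87), the forkhead gene Foxi3 (4.65) and Dusp4 (4.62) were the next largest rises. Sp5 (−5.81), Nkx6-2 (−4.70), Trpm1 (−4.65), Pglyrp1 (−4.60) and Ly6g6e (−4.50) fell furthest. At 12 h the ETS factor gene Etv4, an FGF target, led the rises with 4.71. Formative genes rose by a median of 3.25 at 24 h (13 of 15 called; adjusted p = 4.4e-15; adjusted p = 0.14 with an estimated correlation) and naive genes fell by a median of −2.32 (14 fell, 2 rose; adjusted p = 5.7e-08; adjusted p = 0.14 with an estimated correlation). With limma 497 genes rose and 482 fell by 12 h, and 1060 rose and 1091 fell by 24 h. Of 563 genes called in WT at 12 h, 520 were called the same way in delta (276 rises, 244 falls; 10.6 and 9.14 for independent lists) and 0 the opposite way. At 24 h this held for 1295 of 1427 (659 rises, 636 falls; 55.9 and 53.8 for independent lists), with 1 called the opposite way. Across genes, which are not independent replicates, the changes of the genotypes correlated at Pearson r = 0.86 (Spearman 0.87) at 12 h and 0.89 (0.88) at 24 h. WT and delta libraries of the same number deviated together, most at 0 h (0.70), so these overlaps are not independent of the sampling. Delta counts moved with single libraries, from 173 without delta 12 h replicate 1 to 4522 without delta 0 h replicate 2 at 12 h, and from 789 without delta 24 h replicate 2 to 5080 without delta 0 h replicate 2 at 24 h.

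At 0 h, before induction, delta cells differed from WT in the imprinted gene Mest (ENSMUSG00000051855), which is expressed from the paternal allele and encodes a member of the alpha/beta hydrolase fold family. Mest stood at 8.13 ± 1.20 FPKM in WT and 0.992 ± 0.00462 in delta (SD, n = 2), a difference of −2.19 ± 0.20 log2 units (SE). It was the only gene that limma called (adjusted p = 0.018); 0 genes were called higher, and 173 were higher and 109 lower at an unadjusted p under 0.05. Without single libraries the call held in 2 of 12 fits (adjusted p = 0.066 to 0.11 in the others). It held with the replicate block (adjusted p = 0.027) and was lost with a block within each time (adjusted p = 0.072), chosen after the data were seen. FGF/ERK targets were lower in delta (median −0.22; camera adjusted p = 0.0030; adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone Etv4 (−2.28), Spry4 (−0.84) and Spred1 (−0.57), feedback and effector genes of the pathway, were lower, while Ier3 stood at 1.11. Glycolysis genes were higher (median 0.28; adjusted p = 0.0030; adjusted p = 0.63 with an estimated correlation), but the replicate pairs went opposite ways (−0.19 and 0.72). p53 targets as a list, with Eda2r at 0.83 and Ccng1 at 0.68 (not called singly), were higher as well (median 0.28; adjusted p = 0.025; adjusted p = 0.63 with an estimated correlation), by 0.74 in pair 1 and −0.02 in pair 2. The FGF/ERK call was lost without either delta library of 0 h (highest adjusted p = 0.47), and glycolysis without WT or delta 0 h replicate 2 (0.96). That of p53 targets was lost without WT 0 h replicate 1 or either delta library of 0 h (0.91). The medians rested on single libraries: FGF/ERK was at 0.020 without WT 0 h replicate 2 and −0.033 without delta 0 h replicate 1, glycolysis at −0.066 without WT 0 h replicate 2, and p53 targets at 0.082 without WT 0 h replicate 1.

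Imprinted genes as a list were lower in delta at 0 h by mean (−0.43) and by test (camera adjusted p = 0.0035; adjusted p = 0.25 with an estimated correlation), while their median was −0.05. The members furthest down were Mest, Peg10 (−1.76), Plagl1 (−1.44) and Igf2 (−1.23), and Mest and Peg10 passed adjusted over the list alone. The list was tested with Mest inside, so its call does not stand apart from that of Mest. The median rested on single libraries, with −0.12 and −0.18 without WT 0 h replicate 1 and 2 and −0.19 and −0.24 without delta 0 h replicate 1 and 2. The levels of Igf2 followed the WT replicate 1 libraries, with 4.16, 3.59 and 2.92 FPKM at 0, 12 and 24 h there and 0.376, 0.805 and 0.832 in WT replicate 2. The reverse held for Plagl1, with 0.543, 0.471 and 0.0899 FPKM in WT replicate 1 and 9.58, 5.06 and 0.857 in WT replicate 2. With the replicate block the fibroblast list (median −0.65, adjusted p = 0.048) and the extracellular matrix list (−0.18, adjusted p = 0.047) also passed as lower in delta at 0 h (adjusted p = 0.62 for both with the block and an estimated correlation). The fibroblast medians of the replicate pairs went opposite ways (−1.34 and 0.20), and those of matrix genes were −0.34 and −0.12. The imprinted call was lost without WT 0 h replicate 1 or either delta library of 0 h (highest adjusted p = 0.30), and with the block within each time (adjusted p = 0.11).

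At 12 h limma called Mest (17.8 ± 4.17 FPKM in WT, 1.74 ± 0.136 in delta, SD, n = 2; −2.76 log2 units, adjusted p = 0.0025) and Tcf15 lower in delta, and 0 genes higher (70 higher and 54 lower at an unadjusted p under 0.05; 0 higher and 1 lower with voom weights). The Mest call was lost without delta 12 h replicate 2 (adjusted p = 0.068). Formative genes were higher in delta, 13 of 15 above 0, with values of 0.85 for Sall2, 0.56 for Lef1, 0.46 for Sox3 and 0.42 for Grhl2, not called singly (median 0.32; adjusted p = 0.0019; adjusted p = 0.65 with an estimated correlation). Sall2 lies in a segment of chromosome 14 with lower levels in WT replicate 2, and without the genes of that segment the median was 0.19 (13 genes, adjusted p = 0.0084; adjusted p = 0.67 with an estimated correlation). That call was lost without WT 12 h replicate 2, where the median was −0.07, or delta 12 h replicate 1. p53 targets (median 0.29, adjusted p = 0.0019) and genes of G2 and mitosis (0.13, adjusted p = 0.034) were higher as well; both were lost (adjusted p = 0.61 and 0.49 with an estimated correlation). Both were also lost without WT 12 h replicate 1, and the mitosis genes without WT 12 h replicate 2 or delta 12 h replicate 1. Over the fits that leave out a single library, the mitosis median ranged from 0.087 to 0.22. Primitive endoderm genes, with the collagen IV genes Col4a1 (−0.72) and Col4a2 (−0.58), were lower (median −0.44, 7 of 7 below 0; adjusted p = 0.0042; adjusted p = 0.22 with an estimated correlation). Fibroblast genes (median −0.87, adjusted p = 8.2e-05) and extracellular matrix genes (−0.29, adjusted p = 0.034) were lower too (adjusted p = 0.49 and 0.65 with an estimated correlation). Col4a1 and Col4a2 belong to both the primitive endoderm and the matrix list, so the calls of these lists are not separate. Fibroblast genes were abundant in the WT replicate 1 libraries alone: Tagln, a smooth muscle and myofibroblast gene, stood at 7.84, 21.1 and 15.2 FPKM at 0, 12 and 24 h there and at 1.16, 2.90 and 2.11 in WT replicate 2. Without WT 12 h replicate 1 the fibroblast, primitive endoderm and extracellular matrix calls were lost (adjusted p up to 0.59), the latter pair also without delta 12 h replicate 1. Without WT 12 h replicate 1 the medians were −0.15 for fibroblast genes, −0.21 for primitive endoderm and 0.12 for p53 targets, and without delta 12 h replicate 1 that of matrix genes was −0.11.

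At 24 h naive pluripotency genes were lower and formative genes higher in delta cells than in WT cells. Nanog, a core factor of the naive state, stood at 32.3 ± 1.64 FPKM in delta and 65.9 ± 3.64 in WT (SD, n = 2; −1.01 ± 0.24 log2 units, SE), Tcl1 at −0.73, Nr5a2 at −0.53 and Jam2 at −0.43, and 19 of 20 naive genes were below 0 (median −0.45). Fgf5, a marker of the formative epiblast, stood at 21.7 ± 4.17 FPKM in delta and 9.78 ± 2.36 in WT (1.08 ± 0.24), Sall2 at 0.90, the carbonic anhydrase gene Car4 at 0.79 and Lin28b at 0.46, and 14 of 15 formative genes were above 0 (median 0.46). By camera both lists passed, with adjusted p = 1.2e-11 for naive and 5.5e-10 for formative genes, and both calls were lost (adjusted p = 0.15 and 0.23 with an estimated correlation). Adjusted over the list alone Nanog and Tcl1 were lower and Fgf5 was higher; over all genes none of these was called (limma adjusted p = 1). The replicate pairs gave naive medians of −0.57 and −0.42 and formative medians of 0.33 and 0.69. Both list calls held without each of the 12 libraries (naive median −0.53 to −0.31, formative 0.33 to 0.70). Only the libraries of 24 h enter these medians, so leaving out a library of another time alters the estimated spread alone. Sall2 and Otx2, a homeobox gene of the formative list, lie in a segment of chromosome 14 with lower levels in WT replicate 2; without the genes of that segment the formative median was 0.45 (13 genes, adjusted p = 5.5e-09; adjusted p = 0.23 with an estimated correlation).

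**Figure D3:**
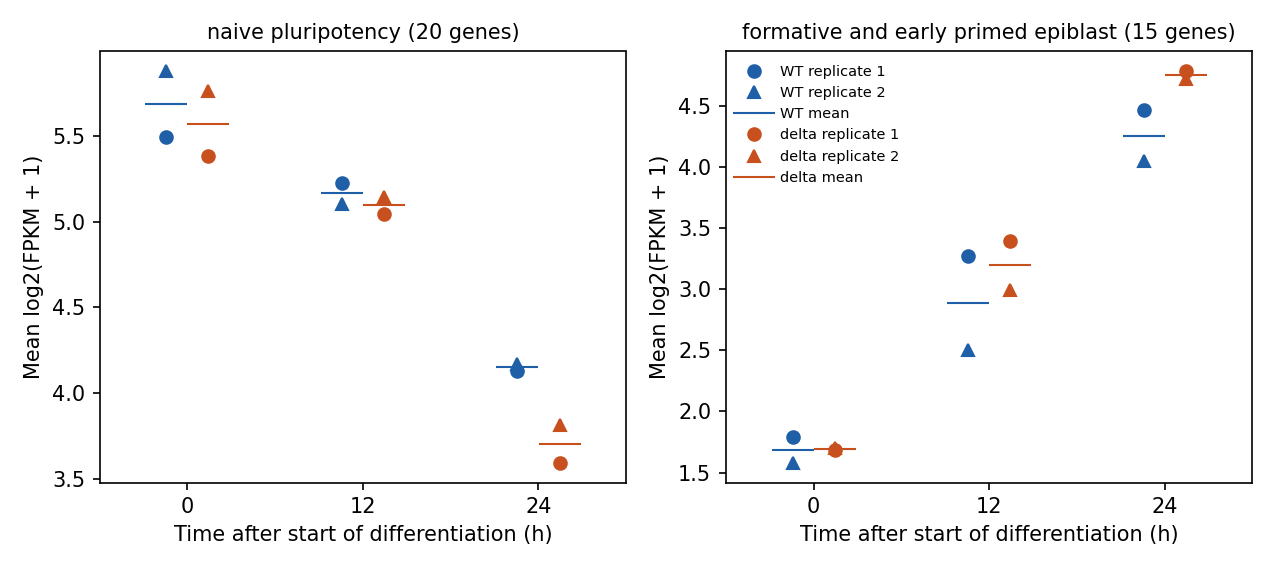
Mean log2(FPKM + 1) of the 20 naive and 15 formative genes in each library by hours of induction; circles are replicate 1, triangles replicate 2, WT blue and delta orange. At 24 h both delta libraries lie below both WT libraries for naive genes and above them for formative genes.

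**Figure D4:**
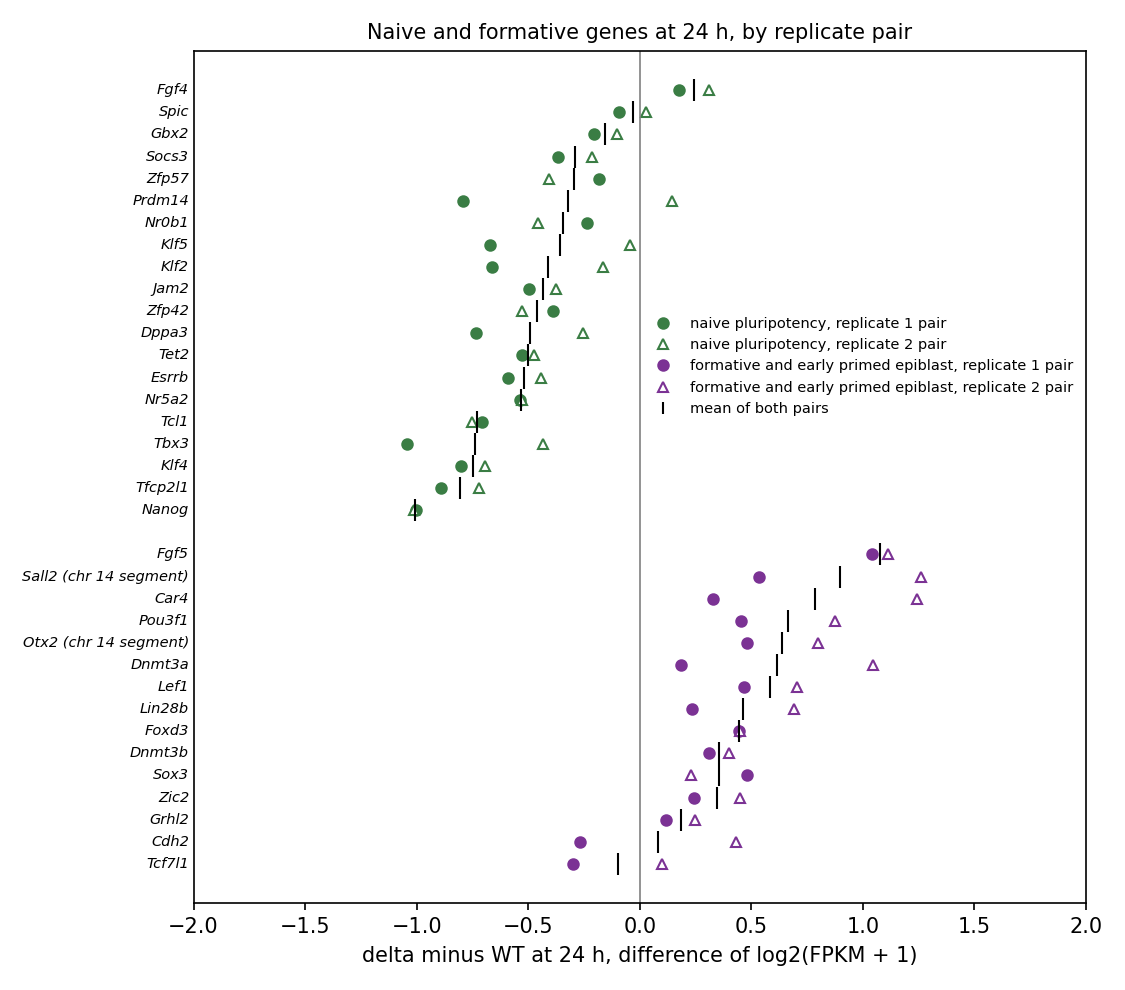
Delta minus WT difference in log2(FPKM + 1) at 24 h for each naive and formative gene; filled circles are the replicate 1 pair, open triangles the replicate 2 pair and black ticks their mean. The means of 19 of 20 naive genes lie below 0 and those of 14 of 15 formative genes above 0.

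Further groups differed at 24 h by the list test. The members named were not called singly, over all genes or over the list alone. The list of p53 targets, genes of apoptosis and cell cycle arrest, was higher in delta with 14 of 15 members above 0 (median 0.38, adjusted p = 8.0e-05; adjusted p = 0.36 with an estimated correlation), among them Pmaip1 at 0.67, Ccng1 at 0.58, Eda2r at 0.56 and Trp53inp1 at 0.45. BMP targets and Id genes were lower (median −0.35, adjusted p = 0.0032; adjusted p = 0.15 with an estimated correlation), with the inhibitory SMAD gene Smad6 at −0.66, Bmp4 at −0.55, Id2 at −0.45 and Id4 at −0.44. Primitive endoderm genes were lower, 7 of 7 below 0 (median −0.28, adjusted p = 0.0069; adjusted p = 0.15 with an estimated correlation), with Col4a1 at −0.87, Col4a2 at −0.55, Lamc1 at −0.38 and Sparc at −0.22. Stress response genes were lower by a median of −0.19 (adjusted p = 0.0070; adjusted p = 0.36 with an estimated correlation), with Trib3 at −0.57, Cth at −0.53, Asns at −0.49 and Ddit4 at 0.59. Fibroblast genes (median −0.73, adjusted p = 0.0050) and extracellular matrix genes (−0.25, adjusted p = 0.0098) were lower too (adjusted p = 0.49 for both with an estimated correlation), with Acta2 at −2.30, Tagln at −1.84, Col1a1 at −1.03 and Nid1 at −0.74. Col4a1, Col4a2, Lamc1 and Sparc belong to both the primitive endoderm and the matrix list, so the calls of these lists are not separate. Acta2, smooth muscle actin, was at 13.5 FPKM in WT 24 h replicate 1 and at 1.19 in WT 24 h replicate 2. Each of these 6 calls was lost without WT 24 h replicate 1, and all but that of fibroblast genes also without a delta 24 h library (replicate 1 for BMP, primitive endoderm and matrix genes, replicate 2 for p53 and stress genes; highest adjusted p = 0.91). Without WT 24 h replicate 1 the medians were −0.010 for p53 targets, −0.010 for stress genes and −0.24 for fibroblast genes. Without WT 24 h replicate 2 they were 0.88, −0.47 and −1.25. Without delta 24 h replicate 1 BMP targets were at −0.16 and matrix genes at −0.15. With the block within each time the fibroblast call was lost (adjusted p = 0.11).

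The remaining lists did not pass at 24 h. The medians were 0.02 for general pluripotency (adjusted p = 0.82), 0.01 for primitive streak (0.87), −0.21 for trophoblast (0.077), −0.18 for neural (0.30), 0.12 for germline (0.23), 0.03 for DNA methylation enzymes (0.81) and −0.10 for FGF/ERK targets (0.22). They were 0.24 for Activin/Nodal targets (0.49), −0.01 for WNT targets (0.65), −0.22 for adhesion genes (0.65), 0.06 for glycolysis (0.99), 0.04 for cholesterol synthesis (0.82), 0.10 for cell cycle (0.52) and −0.00 for heat shock genes (0.83). They were 0.11 for the interferon response (0.99), −0.05 for mitochondrially encoded genes (0.99), 0.01 for Y-linked genes (0.81) and 0.02 for imprinted genes (0.19). Among single genes limma called Mest alone (36.9 ± 3.11 FPKM in WT, 2.49 ± 0.0223 in delta, SD, n = 2; −3.44 log2 units, adjusted p = 3.6e-04), with 0 genes higher (104 higher and 110 lower at an unadjusted p under 0.05). With the replicate block 2 genes were called, Mest and Tcf15, and with voom weights 1 lower and 0 higher.

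Averaged over the 3 times, Mest and Tcf15 were again the genes lower in delta. Mest, on chromosome 6 from 30723547 to 30748465 (plus strand), differed by −2.80 ± 0.11 log2 units (SE; limma adjusted p = 1.7e-05) and was lower in all 6 replicate pairs, a call that held without each of the 12 libraries. It rose with time in both genotypes, by 2.06 in WT (adjusted p = 3.7e-04) and 0.81 in delta (adjusted p = 0.024) from 0 to 24 h. Copg2, chosen after its values were seen, is a coat protein gene on the opposite strand that shares 912 bases with Mest; it stood at −0.04, −0.30 and −0.68 at 0, 12 and 24 h, and reads of the pair may be shared. By limma 0 genes were called higher (314 higher and 291 lower at an unadjusted p under 0.05; 0 higher and 2 lower with voom weights). Of the lists, naive (median −0.18, adjusted p = 9.6e-05), primitive endoderm (−0.41, 0.0013), fibroblast (−0.75, 2.5e-04), extracellular matrix (−0.28, 0.0034), FGF/ERK (−0.12, 0.0053), BMP (−0.17, 0.014) and trophoblast genes (−0.23, 0.043) were lower, and formative genes (0.31, 2.6e-04) and p53 targets (0.29, 9.6e-05) higher. With an estimated correlation the adjusted p were 0.22, 0.22, 0.40, 0.40, 0.36, 0.22, 0.40, 0.40 and 0.36 in that order. The primitive endoderm and extracellular matrix lists share members. Imprinted genes were lower by mean (−0.34) and test (adjusted p = 0.039; adjusted p = 0.22 with an estimated correlation) while their median was 0.06. That median was −0.044 without WT 0 h replicate 1 and −0.058 without delta 0 h replicate 2. Mest lay inside the tested list. The replicate block ended the trophoblast (adjusted p = 0.085) and imprinted (0.12) calls, and the block within each time also that of BMP targets (0.11). Naive, formative, primitive endoderm and p53 calls held without each of the 12 libraries. Their medians moved to −0.28 for naive genes without WT 0 h replicate 1 and 0.16 for formative genes without WT 12 h replicate 2 (0.20 without WT 0 h replicate 2). Primitive endoderm genes were at −0.20 without WT 0 h replicate 2, and p53 targets at 0.17 and 0.45 without WT 24 h replicate 1 and 2. The fibroblast call also held (−0.48 without WT 12 h replicate 1). Leaving out single libraries does not remove what the WT replicate 1 libraries share. Fibroblast medians at 0, 12 and 24 h were −1.34, −1.71 and −1.31 in the replicate 1 pairs and 0.20, −0.12 and −0.17 in the replicate 2 pairs. Those of p53 targets were 0.74, 0.50 and 0.48 against −0.017, 0.14 and 0.25, and those of primitive endoderm −0.29, −0.71 and −0.32 against −0.14, −0.21 and −0.19. The mean level of p53 targets was lower in WT replicate 1 (4.09, 4.40 and 4.04 log2 units) than in WT replicate 2 (4.59, 4.78 and 4.84). Each of the others was lost without at least 2 single libraries, among them delta 0 h replicate 1 in every case (adjusted p up to 0.46). Matrix genes were then at 0.036 and trophoblast genes at −0.10, and without WT 0 h replicate 2 FGF/ERK targets were at −0.018 and BMP targets at −0.099.

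The difference between genotypes in the change from 0 h was tested directly. Formative genes rose further in delta by 24 h, by a median of 0.53 log2 units (camera adjusted p = 3.1e-07; adjusted p = 0.41 with an estimated correlation), with Fgf5 at 1.05, Foxd3 at 0.90, Car4 at 0.78 and Dnmt3b at 0.71, and this held without each of the 12 libraries (0.29 to 0.74). Naive genes fell further, by −0.39 (adjusted p = 2.4e-04; adjusted p = 0.41 with an estimated correlation), with Nanog at −1.09, Tcl1 at −0.55, Klf2 at −0.53 and Jam2 at −0.50. The naive call was lost without WT 0 h replicate 1, delta 0 h replicate 2 or delta 24 h replicate 1, with medians down to −0.08. Stress response genes fell further in delta by 24 h (−0.44, adjusted p = 8.7e-04; adjusted p = 0.41 with an estimated correlation), with Asns at −0.55 and Trib3 at −0.48; without WT 0 h replicate 2, WT 24 h replicate 1 or either delta library of 0 h that call was lost (adjusted p up to 0.28). With the replicate block they also differed at 12 h (−0.19, adjusted p = 0.025; adjusted p = 0.72 with the block and an estimated correlation), which did not pass without the block (adjusted p = 0.052). No single gene passed limma in either contrast (0 called; 86 genes at an unadjusted p under 0.05 for 12 h and 138 for 24 h; 0 with voom weights).

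Genes that changed at least 2-fold from 0 h in the average of both genotypes changed slightly more in delta than in WT libraries. This selection is neutral only where both genotypes vary alike. At 0 h the SD of the log2 difference between replicates was larger in delta (0.83) than in WT (0.66). At 12 and 24 h it was smaller in delta (0.31 and 0.34) than in WT (0.42 and 0.39). The sets may thus favour genes whose change in delta was raised by spread at 0 h, so they cannot decide whether delta cells changed more. Of 798 risen genes 68.0% and of 850 fallen genes 77.8% had moved further in delta at 24 h, by a median of 0.14 and 0.23 log2 units (camera p = 3.5e-08 and 1.8e-12; p = 0.10 and 1.3e-04 with an estimated correlation). At 12 h this held for 70.8% of 510 risen and 75.4% of 483 fallen genes, by 0.15 and 0.16 (p = 9.5e-08 and 6.8e-09; p = 0.092 and 0.0077 with an estimated correlation). With fry, p was 0.34 for risen and 0.0011 for fallen genes at 24 h, and 0.35 and 0.065 at 12 h. The medians of these sets rested on single libraries. Without WT 0 h replicate 1 they were 0.02 and 0.04 at 24 h and 0.05 and 0.06 at 12 h and did not pass, and without WT 0 h replicate 2 those at 12 h were −0.07 and −0.09.

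By chromosome, genes of chromosome 14 were higher in delta: the median averaged difference of its 479 genes lay 0.15 log2 units above the autosomal median (permutation test, adjusted p = 2.1e-04), and 74.3% of its genes lay above. The shift was 0.04, 0.06 and 0.04 in the replicate 1 pairs at 0, 12 and 24 h and 0.27, 0.28 and 0.26 in the replicate 2 pairs. The WT replicate 2 libraries were lower than WT replicate 1 from 47367751 to 70766628 (23.4 Mb, from the galectin gene Lgals3 to Xpo7), with a median of −0.60 over 125 genes (permutation p = 0.001, the smallest possible). Delta libraries of different number differed there by −0.10, −0.02 and −0.01. In the scan of delta replicate 2 against WT replicate 2 the segment ran on to 75.8 Mb (135 genes, permutation p = 0.001), so its end is not sharp. Smaller shifts passed the permutation test on chromosomes 5 (−0.02, adjusted p = 0.033), 8 (−0.03, 2.6e-04), 11 (−0.02, 2.1e-04), 13 (0.04, 2.1e-04) and X (0.03, 3.4e-04). At 24 h alone those of chromosomes 5, 13 and X were −0.0041, 0.0018 and 0.0024. The permutation p-values take genes as the units and hold no spread between libraries, so such small shifts may not recur in other libraries.

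**Figure D5:**
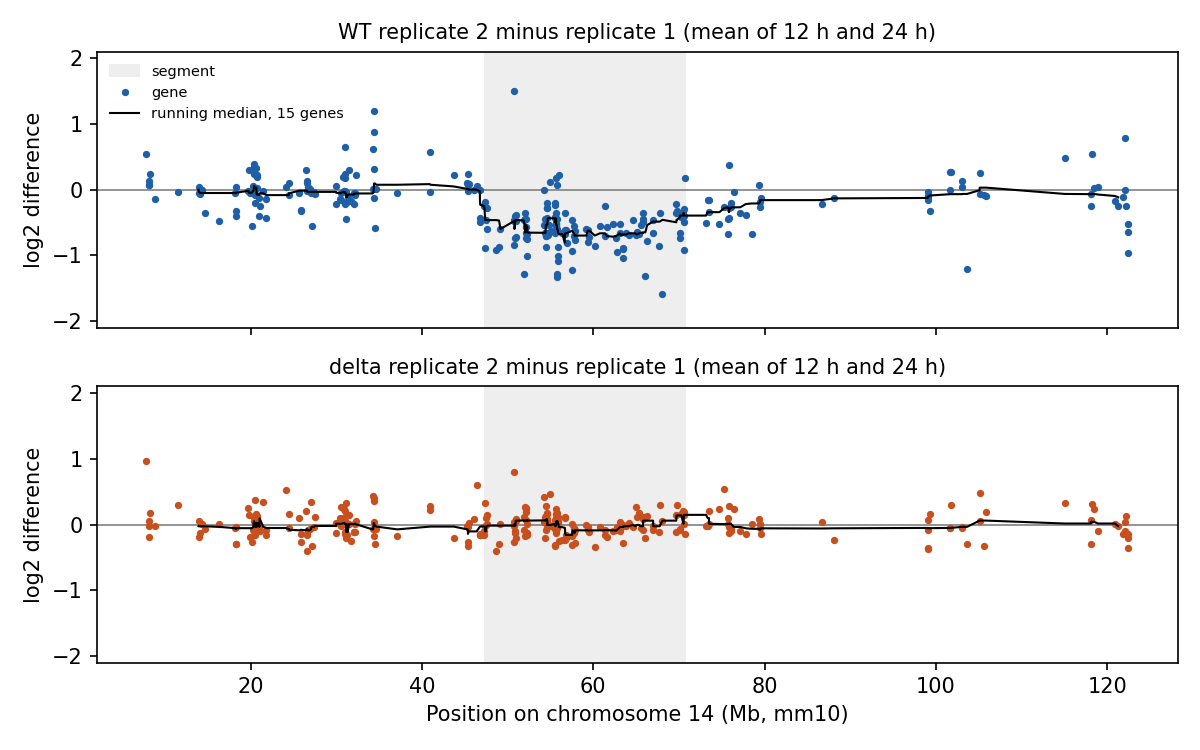
Replicate 2 minus replicate 1 log2 difference of genes along chromosome 14 (x axis, Mb), mean of 12 h and 24 h, for WT (top) and delta (bottom); points are genes, the line is a running median of 15 genes (points beyond ±2 are drawn at ±2) and grey marks the segment from 47.4 to 70.8 Mb. The WT points inside the segment lie around −0.60, while delta points lie around 0.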

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

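The tests of a wider loss at imprinted genes, of Mest against Tcf15 loss, of a difference at 0 h, of progress with time, of the whole chromosome 14 and of the WT replicate 2 segment were chosen after the results were seen.

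With camera at the preset correlation, the difference between genotypes in the change from 0 h passed in 8 tests of 6 gene lists. It also passed for all 4 sets of changing genes. With an estimated correlation none of the list tests passed, those of naive, formative and stress response genes included. By 12 h formative genes changed by 0.35 log2 units more in delta than in WT (camera adjusted p = 0.0027; adjusted p = 0.71 with an estimated correlation). Glycolysis genes differed by −0.24 (adjusted p = 0.0027; adjusted p = 0.71 with an estimated correlation), with Aldoc at −0.67 and Slc2a1 at −0.40. Genes of G2 and mitosis differed by 0.19 (adjusted p = 0.0027; adjusted p = 0.57 with an estimated correlation), with Plk1 at 0.38 and Top2a at 0.37. By 24 h the differences were −0.39 for naive genes, 0.53 for formative genes, 0.27 for FGF/ERK targets (adjusted p = 0.048; adjusted p = 0.46 with an estimated correlation), −0.29 for glycolysis genes (adjusted p = 0.0036; adjusted p = 0.57 with an estimated correlation) and −0.44 for stress response genes. The FGF/ERK members went both ways, with Etv4 at 1.59 and Ier3 at −1.49, and that call held without 3 of the 12 libraries. The sets of genes that had changed at least 2-fold were picked on the average change, which can favour delta, the more variable genotype at 0 h. These genes moved further in delta by 0.15 (risen) and 0.16 (fallen) at 12 h and by 0.14 and 0.23 at 24 h. Of all these, the formative difference at 24 h was the one whose call held without each of the 12 libraries. Without WT 0 h replicate 1 the medians of the 4 sets were 0.05, 0.06, 0.02 and 0.04, and without WT 0 h replicate 2 those of 12 h were −0.07 and −0.09. Some list medians turned without a single library: formative at 12 h to −0.018 without WT 12 h replicate 2, glycolysis to 0.034 at 12 h and 0.11 at 24 h without WT 0 h replicate 2, and FGF/ERK to −0.014 without delta 0 h replicate 1. The G2 and mitosis median was 0.092 without WT 0 h replicate 1 and 0.096 without delta 0 h replicate 2, naive −0.082 and −0.096 without the same libraries, and stress −0.11 without WT 0 h replicate 2.

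Mest was lower in delta cells at each time, by −2.19, −2.76 and −3.44 log2 units. With a pseudocount of 0.1 the differences were −2.91, −3.26 and −3.84, and with voom weights −3.01, −3.31 and −3.89. The pseudocount of 1 thus understates them, most at 0 h. A copy loss that reaches the neighbours of Mest is argued against by their values. The 6 other expressed genes within 500 kb, without Copg2, had a median difference of −0.047 (−0.16 to 0.053), where the loss of 1 copy of 2 would give −1. The nearest of them was Cep41 at 29.8 kb, and on the side of Copg2 it was Gm13835 at 393.5 kb. A smaller loss at Mest itself would leave these genes unchanged and remains open. A wider loss at paternally expressed imprinted genes remained open, since the 7 others measured had a median of −0.15 and went both ways, from −1.23 (Igf2) to 0.24 (Snrpn), genes chosen after their values were seen. Whether Tcf15 loss or a property of the single clone lowered Mest cannot be told apart, since the difference was −2.19 already at 0 h, where Tcf15 itself stood at only 6.31 FPKM in WT. A silenced paternal allele in the clone is a candidate explanation that no value here tests.

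Naive genes were lower and formative genes higher in delta cells at 24 h. The formative minus naive genotype difference was 0.94 ± 0.12 at 24 h (SD over 2 replicate pairs), 0.38 ± 0.10 at 12 h and 0.12 ± 0.17 at 0 h. For naive genes a difference as large at 0 h as at 24 h is argued against. Their pair medians were −0.12 and −0.15 at 0 h and −0.57 and −0.42 at 24 h. Formative genes cannot decide this, since their mean level at 0 h was only 1.58 to 1.79 log2 units, where the pseudocount of 1 understates differences. Bias by transcript length and GC content is also argued against, since removing that trend (SD 0.027 log2 units, 99.7% of genes) left the difference at 0.94. Delta cells may lie further along the whole change with time at 24 h: of 368 other genes that changed at least 2-fold from 12 to 24 h, 83.2% and 82.9% lay further along in delta in the pairs, which goes against an effect confined to these lists. The single clone leaves open whether the deletion or the clone is behind it.

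Genes of chromosome 14 were higher in delta cells by 0.15. An extra copy of the whole chromosome in part of the delta cells was first tested over 4 equal blocks of the chromosome. They met neither bound written before that result (lowest block 0.03). The test was then extended to replicates, with a mean shift of 0.047 in the replicate 1 pairs against 0.26 to 0.28 in the replicate 2 pairs. This cannot decide the question, since the replicate 2 pairs hold the segment that was lower in WT replicate 2. Delta replicate 2 minus WT replicate 2 was 0.63 to 0.69 inside that segment and 0.04 to 0.10 on the rest of the chromosome. An extra copy in part of the cells remains open. Length and GC bias is argued against, since the shift was 0.15 log2 units before and still 0.13 after removing that trend. Lower levels of a 23.4 Mb segment in the WT replicate 2 libraries were found from 12 h and 24 h and then seen at 0 h too (median −0.65), while delta libraries differed there by −0.10, −0.02 and −0.01. A loss of that segment in part of the WT replicate 2 cells may account for this, as a hypothesis that no value here tests. Further biological explanations were not tested.

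The 2 genes called in the genotype effect averaged over times were set against other splits of the 4 libraries of each time. Of 100 splits drawn from 108, 17 gave at least 2 genes, so this count by itself does not exclude a split by chance. The highest other count, 4807 genes, came from the split that follows the replicate number, which points to a structure of the samples by replicate. With a block for the replicate pair within each time, 4 genes were called, and only 1 of the 32 splits that swap genotypes within pairs, the real one, gave as many; the highest other was 2.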

How the results depend on the processing

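The block within each time, the fits without both replicate 1 libraries of 0 h, without the 2 libraries richest in rRNA-like reads, with 12 h and 24 h only, with protein-coding genes only and without the chromosome 14 segment, and the lists without each library, were chosen after the data were seen; the other alternatives were planned. For every change below the cause was not tested, unless fewer genes or libraries in the fit are named. Counts are of genes called by limma, and p are adjusted over genes, lists or chromosomes, except for the sets of changing genes.

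With no filter on low values 6 genes were called at 0 h, 18 at 24 h and 10 averaged over times, and 5 and 13 for the differences in change to 12 and 24 h. Apart from Mest and Tcf15, these were mostly predicted genes (Gm followed by digits), with differences of at most 1.17 log2 units in either direction. Tcf15 at 12 h (−4.34) had a limma adjusted p of 0.12 in that fit. A minimum FPKM of 5 left fewer genes, with 920 called in WT and 1408 in delta by 24 h, a correlation of changes of 0.92, and a shift of chromosome 19 that passed (−0.027, permutation test, adjusted p = 0.028). With a pseudocount of 0.1 that correlation was 0.84 and chromosome 5 did not pass (−0.018, permutation test, adjusted p = 0.053). Quantile normalization called 1 gene at 12 h and gave Tcf15 there −4.43 (adjusted p = 0.060); it moved the median of all genes by at most 0.069 log2 units, and median-of-ratios scaling by 0.028. Without a variance trend 1 gene was called at 12 h (Tcf15 −4.34, adjusted p = 0.050), and with voom weights 1. Fits with only the groups compared, which hold 4 libraries, called 0, 0 and 0 genes between genotypes at 0, 12 and 24 h, 0 by 12 h in WT and in delta, and 367 (WT) and 335 (delta) by 24 h (Tcf15 at 12 h −4.34, adjusted p = 0.75).

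With the replicate number as a block, 2 genes were called between genotypes at 24 h, Tcf15 passed there (−4.06, adjusted p = 0.0012), and 989 (WT) and 1605 (delta) genes changed by 12 h. Over all 15 pairs of groups the deviations of same-numbered libraries correlated between −0.07 and 0.70, with 14 over 0.1. Apart from the list calls given with each comparison, and extracellular matrix genes that passed in delta by 12 h (0.48, adjusted p = 0.047; adjusted p = 0.61 with an estimated correlation), the pairing changed no other call of a gene list or of a genotype comparison. With a block within each time the genotype counts were 0 at 0 h, 2 at 24 h and 4 averaged over times, with Tcf15 at 24 h passing (−4.06, adjusted p = 0.028).

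Without both replicate 1 libraries of 0 h, each genotype kept 1 library at 0 h, assumed to vary like the other groups; 3 genes were called between genotypes there, Mest not among them (−2.05, adjusted p = 0.082), 1 at 12 h and 5 averaged over times; 1169 (WT) and 2387 (delta) changed by 12 h and 2830 and 3906 by 24 h. Tcf15 at 12 h (−4.34) then had adjusted p = 0.079, and the further movement in delta of the genes risen by 24 h (0.048) no longer passed. Without the libraries richest in rRNA-like reads 0 genes were called at 0 h and 0 at 12 h (Tcf15 −4.83, adjusted p = 0.25), and the genes risen by 12 h turned to −0.014. In that fit formative genes turned to −0.067 at 12 h and to −0.20 for the difference in change, and WNT targets, not called with all libraries, turned to 0.68 at 0 h and to −0.61 and −0.65 for the differences in change. With 12 h and 24 h only, 1 gene was called at 12 h (Tcf15 −4.34, adjusted p = 0.080).

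Leaving out each of the 12 libraries in turn, where the remaining library of a group is assumed to vary like those of the other groups, gave 0 to 1 genes between genotypes at 0 h, 0 to 2 at 12 h, 1 to 2 at 24 h and 2 to 2 averaged over times. For changes it gave 130 to 1084 (WT) and 173 to 4522 (delta) by 12 h, 596 to 2458 and 789 to 5080 by 24 h, and 0 to 1 and 0 to 0 for the differences in change. The WT count by 12 h was 311 without WT 0 h replicate 1, 248 without WT 12 h replicate 2, 350 without either delta library of 12 h, and 358 and 359 without the delta libraries of 24 h. The WT count by 24 h was 702 without WT 24 h replicate 2 and 2451 without delta 0 h replicate 1. The delta count by 12 h was 202 without delta 12 h replicate 2 and 641 and 640 without the delta libraries of 24 h, and that by 24 h was 927 without delta 24 h replicate 1. Tcf15 ranged from −2.0 to −0.81 at 0 h, −4.83 to −3.86 at 12 h, −4.47 to −3.64 at 24 h and −3.47 to −3.07 averaged over times. The further movement of changed genes in delta ranged from −0.072 to 0.46 (risen) and −0.089 to 0.70 (fallen) at 12 h, and from 0.022 to 0.34 and 0.038 to 0.60 at 24 h; 12 h risen genes were at −0.036 without WT 12 h replicate 2, and 24 h risen genes at 0.022 without WT 24 h replicate 2.

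Over all alternatives but voom weights, called genes named here kept their direction and side of the threshold in 5531 comparisons and lost the threshold in 730. Genes not called passed in 266. Lists were counted over fewer alternatives: the pseudocount, median-of-ratios scaling, the replicate block, the estimated correlation, fry, and the later fits except protein-coding genes only. Fits without each single library, which ended many list calls, are not in the list counts. Called gene lists kept theirs in 512, lost it in 165 and reversed in 2. Lists not called passed in 70 and reversed in 3. Limiting the fit to protein-coding genes or leaving out the chromosome 14 segment left the counts between genotypes and the Tcf15 calls as they were; by 12 and 24 h they gave 586 and 1432 or 560 and 1403 genes in WT and 967 and 2044 or 972 and 2126 in delta. Depth was 9740851 to 17571255 reads, so a level under about 0.0569 to 0.111 FPKM rests on under 1 read per kilobase.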

Other observations

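The block within each time was chosen after the results were seen, and Ap1m2, Ephx1 and the genes set out by library after their values were seen; the list tests were planned.

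Genes that were not called over all genes still differed between genotypes in every library pair. Ap1m2, which encodes a subunit of the epithelial AP-1B sorting complex, stood at 7.68 and 8.93 FPKM in WT and at 17.5 and 18.1 in delta at 24 h (averaged difference 0.94 log2 units, limma adjusted p = 0.88). Ephx1, microsomal epoxide hydrolase, stood at 5.56 and 6.92 FPKM in WT and at 8.93 and 9.64 in delta (0.83, adjusted p = 0.37). With the block within each time both passed and were the only genes called higher in delta averaged over times.

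In delta cells imprinted genes rose between 0 and 24 h (median 0.27, camera adjusted p = 0.036; adjusted p = 0.17 with an estimated correlation), among them Peg10 (3.10), Snrpn (2.1), the cell cycle inhibitor gene Cdkn1c (2.1) and Peg3 (1.06). Delta cells also lowered 7 of 15 stress response genes by 24 h (median −1.22, adjusted p = 4.7e-04; adjusted p = 0.17 with an estimated correlation) and glycolysis genes (−0.77, adjusted p = 0.0061; adjusted p = 0.50 with an estimated correlation). In WT cells BMP targets and Id genes rose by 12 h (median 0.79, adjusted p = 0.042; adjusted p = 0.23 with an estimated correlation), and so did extracellular matrix genes (0.63, adjusted p = 0.019; adjusted p = 0.46 with an estimated correlation), with Col18a1 at 2.25.

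Genes of mesenchymal cells were found in the WT replicate 1 libraries at all 3 times. Acta2 stood at 5.21, 14 and 13.5 FPKM at 0, 12 and 24 h there, at 0.216, 0.787 and 1.19 in WT replicate 2 and at 0.416 or less in delta. Col1a1 stood at 2.87, 4.38 and 3.06 FPKM in WT replicate 1 and Col3a1 at 1.56, 2.30 and 1.56. The growth factor gene Igf2 was higher in the same libraries, while Plagl1 was higher in WT replicate 2. Mest did not follow this split, with 8.98 and 7.28 FPKM in the WT libraries of 0 h and 34.7 and 39.1 in those of 24 h. No explanation of the mesenchymal genes was tested.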
